A study of Mus musculus with 15 samples.

How the data were processed

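Expression was measured in colon scrapings of 15 male C57BL/6 mice, 6 fed a control diet and 9 fed the same diet with heme for 14 days, with 1 Affymetrix mouse expression array per mouse and no pooling. Per the submitters' processing notes, the authors made the deposited values with GCRMA 2.22.0, which corrects background from probe sequence, normalizes between arrays and summarises probes. The deposited values are log2 expression per probe set. Further steps are not given in the sources used here, nor are detection calls, so a signal of 20 (4.32 on the log2 scale) served as a floor. The number of arrays limits the precision.

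Probe sets were matched to gene symbols with the annotation of the array. Of the probe sets 34958 had 1 symbol, 932 had several and 9211 were not listed, and only those with 1 symbol stood for genes. A gene was represented by its probe set with the highest mean over all arrays. Genes with a signal over 20 on at least 6 arrays were tested, 9257 of 18194. Heme was compared with control by limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. Fold changes are heme minus control on the log2 scale with their standard error. Where every array of a group lay at or under the floor, the fold was computed against the floor and is given as "at least". Where most arrays of a group did, among named genes Gzma, Wif1, Shh, Slc46a1 and Dclk1 in heme mice and Ly6m, Ereg and Btc in controls, the size of a change is uncertain.

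Before the data were examined, 35 gene lists were fixed, covering pathways and markers of the cell types a colon scraping can hold. Of these 30 had at least 2 tested members and were tested with camera (limma) against all other tested genes, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. Members were counted over all tested genes and adjusted over the list alone. Those 2 counts were equal except for DNA replication genes. Of the 12 lists called, 5 higher and 7 lower, 0 were called with an estimated correlation. RNA integrity was checked with an exact two-sided permutation test of the array control probe sets over 5005 splits, where the smallest p possible is 0.0002.

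The rule for named genes, also fixed before, took the 10 genes with the largest rise and the 10 with the largest fall among called genes whose groups do not overlap. Symbols that are not names (Gm, LOC, Rik, clone or expressed-sequence identifiers) were left out of this ranking. The rule added the 2 members of each list with the largest called change (1 for lists of non-epithelial cells) and a fixed set with Wif1, Ihh, Bmp2, Il15, Hmox1, Mki67, Birc5, Ppara, Lgr5, Areg and Ereg. Of these Areg was not analysed here, and 63 genes were named. All other genes given by name, and the values of single mice, were chosen after their values were seen. For 18 of the 63, more than 1 probe set lay over the floor, and in all 18 these moved in 1 direction. The size of the log2 fold change could differ between them. It was 1.98 and 3.64 for Gsta3, 1.00 and 1.69 for Gins2, -0.75 and -1.40 for Dclk1 and -4.20 and -5.80 for Slc30a10. For others it was close, such as 3.58 and 3.64 for Me1.

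The alternatives fixed beforehand were no signal filter, a floor of 100, the mean of a gene's probe sets, median centring, quantile normalization, trend and robust variance, array weights, the replicate number as a block, array number as a covariate, and leaving out each mouse in turn. With the block, heme mice 5, 8 and 9, whose numbers no analysed control shares, add nothing to the contrast. For lists, fry, camera on ranks and an estimated correlation were also fixed. Chosen after the data were seen were leaving out control mouse 2 with heme mouse 6, leaving out these and control mouse 4, a smooth muscle covariate (the mean of smooth muscle markers) and a distal Hox covariate (the mean of 3 distal Hox genes). The gene calls were compared with those of 100 random splits of the mice into groups of 6 and 9. Tested on simulated data with 50 changed genes per size, the procedure found 26% of changes of 0.25 on the log2 scale, 76% of 0.5, 94% of 1 and 100% of 2, with 10 unchanged genes among 158 calls. The simulation changed 200 of 9257 genes, whereas 53.6% of the real genes were called. With so few changed genes the adjusted threshold is stricter, so these rates do not give the sensitivity in the real data. A simulated shift of 0.5 in the mitosis list was called, with 0 other lists. Simulated genes varied independently of each other, whereas the estimated correlation among the real mitosis genes was 0.761. The simulation therefore does not show how often correlated lists are called by chance. Control replicate 5 was not analysed here, and probe sets with several symbols or none were left out of the gene comparison.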

Results

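Gene expression was measured in scrapings of the colon of male C57BL/6 mice, a common inbred laboratory strain. For 14 days the mice ate a high-fat, low-calcium diet, with 40% of its energy as fat, either without heme (control, 6 mice) or with heme at 0.5 umol per g (heme, 9 mice). Heme is the iron-porphyrin pigment of red meat. The labels state that each mouse was analysed on its own, so each of the 15 arrays is 1 animal and the replicates are biological. Control replicate 5 was not analysed here. The arrays report log2 expression per probe set, and 34958 probe sets have 1 gene symbol and stand for 18194 genes. On each array between 9066 and 9319 genes lay over the signal floor of 20, and 9257 genes did so on at least 6 arrays and were tested. Array medians ran from 3.11 to 3.24 on the log2 scale. The number of arrays limits the precision. The design poses 1 comparison, heme against control, and the series title sets its question, the part that inhibitors of proliferation play in the turnover of the epithelium. No genome was used here, so positions are not given and genes are identified by symbol.

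Between the colon scrapings of heme and control mice, 4961 of the 9257 tested genes differed. Slpi, a secreted inhibitor of leukocyte proteases, rose 80.7-fold, from 4.99 ± 0.30 in control mice (log2, SD, n = 6) to 11.33 ± 0.93 in heme mice (n = 9). Fabp1, a fatty acid binding protein, rose 70.1-fold, from 7.00 ± 1.18 to 13.13 ± 0.41. Hmox1, the enzyme that opens the heme ring, was under the signal floor in all control mice at 3.46 ± 0.32 and reached 8.85 ± 0.78 in heme mice, at least 23.1-fold higher. In the other direction Slc30a10, a manganese exporter, was at 7.94 ± 0.85 in control mice and under the floor in all heme mice at 2.13 ± 0.20, at least 12.3-fold lower. Slc13a1, a sulfate transporter, fell by 4.48 ± 0.30 on the log2 scale (SE, adjusted p = 2.72e-08, limma).

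The other large rises were in Ly6m (log2 fold change 4.40 ± 0.25, SE), Sprr1a, a cornified envelope precursor (3.65 ± 0.37), the glutathione transferase Gsta3 (3.64 ± 0.23), the carbonyl reductase Cbr3 (3.59 ± 0.08), the lipoprotein Apoc2 (3.59 ± 0.32) and malic enzyme Me1 (3.58 ± 0.32). Gsta2 was under the floor in all control mice and at least 4.49-fold higher in heme mice. The other large falls were in Cubn, the intestinal receptor for vitamin B12 bound to intrinsic factor (-3.95 ± 0.30), the lymphocyte protease Gzma (-3.59 ± 0.24), the ileal bile acid binding protein Fabp6 (-3.58 ± 0.27), endothelin Edn1 (-2.98 ± 0.33), Ifit1bl2 (-2.94 ± 0.33), serum amyloid Saa3 (-2.94 ± 0.28) and chromogranin Chga (-2.86 ± 0.19). Resp18, a secretory granule protein, was at least 5.65-fold lower in heme mice, all of which lay under the floor. These 20 genes were picked among called genes whose groups do not overlap, so in each all 9 heme mice lay beyond all 6 controls by that rule. The highest adjusted p among them was 3.58e-06 (limma). Genes with overlap were left out whatever their change, such as Dbp at -2.862 beside Chga at -2.857. Genes whose symbol is not a name, such as Gm or Rik identifiers, were left out too. Probe sets of the Gsta, Ly6, Saa and Ifit families can bind transcripts of close relatives, so which family member changed is uncertain. Gzma lay under the floor in 8 of 9 heme mice and Ly6m in 4 of 6 controls, so the size of their change is set partly against background.

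**Figure D1:**
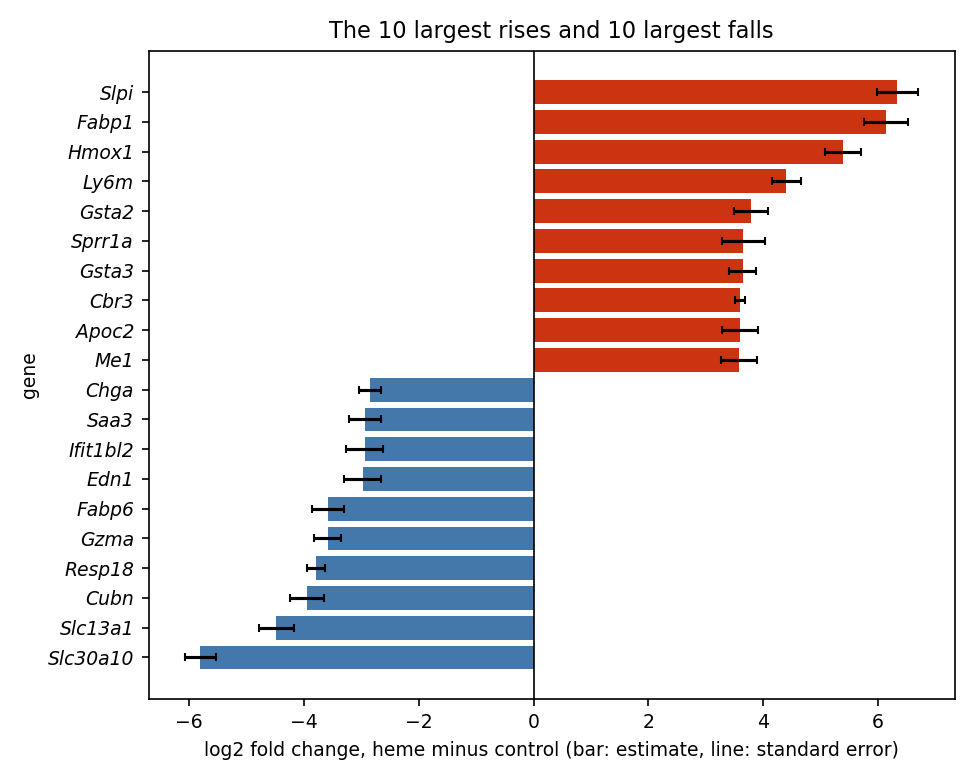
Horizontal bars give the fitted log2 fold change, heme minus control, and lines give its standard error, from 6 control and 9 heme mice. Shown are the 10 largest rises and the 10 largest falls among called genes with no overlap between groups and a name as symbol. Slpi is at 6.33 and Slc13a1 at -4.48; for Hmox1, Gsta2, Slc30a10 and Resp18 one group lay under the signal floor, so the bar is set against background, their fold is only bounded and their rank is not known.

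In all, 2516 genes were higher and 2445 lower with heme at an adjusted p under 0.05 (limma, Benjamini-Hochberg), 53.6% of those tested. Most changes were small, with 506 genes at a fitted change of at least 2-fold, 276 up and 230 down. With genes under the floor in all mice of a group set at their bound, 258 were up and 222 down at least 2-fold, and 15 up and 5 down at least 8-fold. The values of the groups did not overlap for 1041 genes that were higher and 827 that were lower, where chance gives 0.02% of genes per direction. The median log2 fold change of all tested genes was -0.01. The first principal component held 53.3% of the variance and set all heme mice (9.05 to 25.9) apart from all controls (-35.7 to -25.6). The second held 14.6% and set control mouse 2 (33.5) and control mouse 4 (-33.4) apart from the rest. Control mouse 2 was rich in stromal and muscle transcripts, with decorin (Dcn) at 10.41 against 6.37 ± 0.82 (SD) in the other 5 controls. Control mouse 4 was low in transcripts of the distal colon, with Hoxb13 at 3.77 against 11.01 ± 0.81. Heme mouse 6 was high in interferon-induced transcripts, with Gbp2 at 11.28 against 5.14 ± 0.32 in the other 8 heme mice. Without these 3 mice 2359 genes were higher and 2388 lower, a choice made after the values were seen.

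The 4 inhibitors of proliferation that the study names all fell. Wif1, a secreted antagonist of Wnt ligands, fell from 6.30 ± 0.62 to 4.15 ± 0.31 (SD, n = 6 and 9), a log2 fold change of -2.15 ± 0.22 (SE, adjusted p = 1.63e-06, limma). Il15, an interleukin made by epithelial and immune cells, fell by 1.98 ± 0.33 (adjusted p = 1.35e-04). Bmp2, a bone morphogenetic protein that restrains the crypt, fell by 0.98 ± 0.16 (adjusted p = 1.29e-04), and Ihh, the hedgehog ligand of mature colonocytes, fell by 0.51 ± 0.11 (adjusted p = 8.95e-04). All 9 heme mice lay under all controls for Wif1, Il15 and Bmp2, and 8 of 9 for Ihh. Wif1 lay under the floor in 7 of 9 heme mice, so the size of its fall is set partly against background. The median change of the 4 was -1.48, and all 4 also passed adjusted over the list alone. The study chose these genes on these or matching samples, so their direction is not independent evidence. As a list they were lower than other genes (camera, adjusted p = 0.00714), with adjusted p = 0.14 with an estimated correlation. Smooth muscle markers, lower in heme mice too, tracked part of the Bmp2 difference, which was -0.51 with adjusted p = 0.0527 once the smooth muscle score was a covariate.

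Genes of cell division rose together. All 26 tested mitosis genes rose, with a median log2 fold change of 1.07. The mitotic kinases Plk1 (1.83 ± 0.21, SE) and Aurka (1.77 ± 0.23) rose most, Birc5 (survivin, which acts in mitosis and against apoptosis) rose by 1.34 ± 0.14, and Mki67, the proliferation marker Ki-67, by 0.62 ± 0.09, each in all 9 heme mice above all 6 controls. With the probe sets of a gene averaged, the change of Aurka was 0.92, but only 1 of its 2 probe sets lay over the floor on enough arrays. Of 24 DNA replication genes 21 rose and none fell, with a median of 0.73, or 0.69 with members under the floor in one group set at their bound. Among them were Rrm2, a subunit of the ribonucleotide reductase (1.70 ± 0.15), and Gins2, of the replicative helicase (1.69 ± 0.16), and adjusted over the list alone 22 rose. The 3 without a call were Cdt1 (0.27 ± 0.14), Rfc3 (0.29 ± 0.13) and Mcm6 (0.30 ± 0.13). Both lists were higher than other genes (camera, adjusted p = 3.29e-12 and 5.34e-08). Their adjusted p = 0.224 and adjusted p = 0.234 with an estimated correlation did not pass. Mean mitosis expression was 7.37 ± 0.39 (SD) in control and 8.48 ± 0.15 in heme mice, with control mouse 4, low in distal colon transcripts, the highest control at 7.97.

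**Figure D2:**
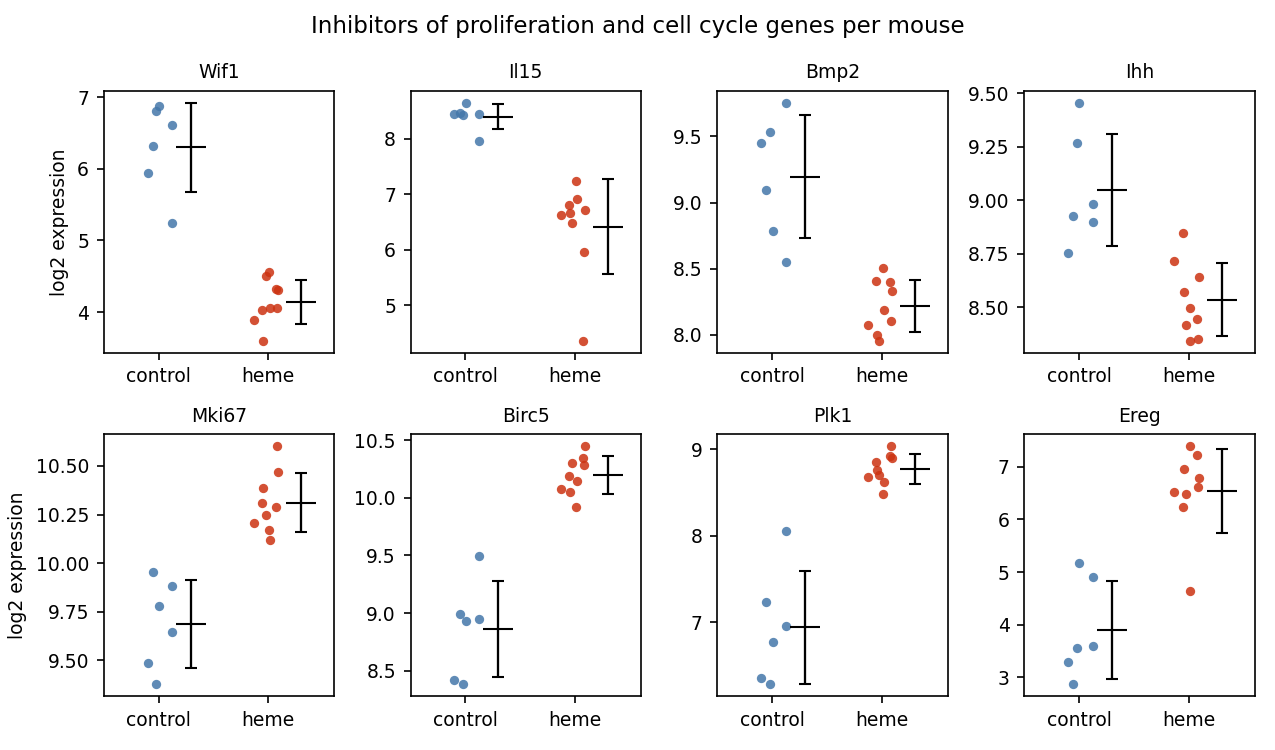
Each panel plots the log2 expression of 1 gene, with a point per mouse and a line at the group mean with its SD (6 control, 9 heme mice); each panel has its own vertical scale. Wif1, Il15, Bmp2 and Ihh are lower with heme, with mean changes of -2.15, -1.98, -0.98 and -0.51, while Mki67, Birc5, Plk1 and Ereg are higher.

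Of 13 tested crypt base and Wnt target genes 7 fell, 1 rose and 5 were not called, with a median of -0.46. Rnf43, a ubiquitin ligase that limits Wnt receptors, fell by 1.09 ± 0.11 (SE), and Lgr5, the receptor that marks crypt base stem cells, fell by 0.94 ± 0.14, both in all 9 heme mice below all controls. The gene that rose was cyclin Ccnd1 (0.25 ± 0.09), and without control mouse 3 or control mouse 4 the count of crypt base and Wnt target genes that rose was 0. The list was lower than other genes (camera, adjusted p = 0.00714), with adjusted p = 0.219 with an estimated correlation. It did not pass at a signal floor of 100 (adjusted p = 0.258) or with the smooth muscle score as a covariate (adjusted p = 0.0535), and over all camera alternatives the crypt base and Wnt target list ran from 0.00262 to 0.258. Wif1 was the only secreted Wnt inhibitor of the 10 listed that was over the floor. Of 6 Hedgehog pathway genes 4 fell and none rose, the ligand Shh by 0.85 ± 0.18, the receptor Ptch1 by 0.75 ± 0.10, Ihh and the co-receptor Boc (-0.50 ± 0.13). With probe sets averaged Ptch1 fell by 0.48, but only 1 of its 3 probe sets lay over the floor on enough arrays. As a list the Hedgehog genes were not called (camera, adjusted p = 0.0846), but were without a signal filter (0.0396) and with the replicate block (0.0496). BMP pathway genes went both ways, 3 up and 5 down of 13 (camera, adjusted p = 0.572), with Bmp8b, under the floor in all controls, at least 1.13-fold higher beside the fall of Bmp2. EGF family genes went both ways, 3 up and 3 down of 9. Epiregulin (Ereg) rose by 2.64 ± 0.41, betacellulin (Btc) by 0.78 ± 0.15 and Tgfa by 0.51 ± 0.12, while the receptors Erbb3 (-0.68 ± 0.11) and Erbb2 (-0.66 ± 0.11) and the receptor inhibitor Lrig1 (-0.40 ± 0.10) fell. Ereg and Btc were above all controls in 8 of 9 heme mice, with 4 and 5 of 6 controls under the floor, and the list was not called (camera, adjusted p = 0.897). Areg, another EGF receptor ligand, was not analysed here.

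Genes of fatty acid use, antioxidant defence and sterol synthesis rose. Of 27 PPAR-alpha targets and fatty acid oxidation genes 22 rose and 1 fell, with a median of 0.74. Beside Fabp1, the transcription factor Creb3l3 rose by 3.20 ± 0.20 (SE). The gene that fell was Ppara itself, the receptor that drives this set (-0.59 ± 0.22, adjusted p = 0.0309, limma), although no heme mouse lay under all controls. That call was lost without control mouse 1, 4 or 6 or heme mouse 4 or 8, each left out singly, where the difference was between -0.42 and -0.58. It was also lost with the replicate number as a block (-0.50, adjusted p = 0.186, limma) and without the 3 mice that stand apart (-0.52, adjusted p = 0.0576, limma). With the smooth muscle covariate Ppara was at -1.04. Of 24 Nrf2 targets and antioxidant genes 22 rose and 1 fell, with a median of 0.96, led by Hmox1 and Gsta3, and the one that fell was the epoxide hydrolase Ephx1 (-0.66 ± 0.09). Of 18 cholesterol synthesis genes 15 rose and 1 fell, with a median of 0.82. Farnesyl diphosphate synthase (Fdps) rose by 2.06 ± 0.18 and mevalonate decarboxylase (Mvd) by 1.55 ± 0.15, and the one that fell was the sterol carrier Stard4 (-0.22 ± 0.05). With probe sets averaged Fdps rose by 1.05, but only 1 of its 2 probe sets lay over the floor on enough arrays. In all 3 lists the counts were the same adjusted over the list alone. The lists were higher than other genes (camera, adjusted p = 2.82e-10, 1.43e-11 and 3.47e-07 in that order). With an estimated correlation they gave adjusted p = 0.219, adjusted p = 0.14 and adjusted p = 0.185.

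Of 20 genes that handle heme and iron 7 rose, 4 fell and 9 were not called, and the list did not differ detectably from other genes (camera, adjusted p = 0.297). The median change of the list was 0.06 and its mean 0.30, which rests on Hmox1, since the other 19 averaged 0.03. Against no change fry gave adjusted p = 2.51e-05. Hmox1 rose, the heme and folate carrier Slc46a1 fell by 2.85 ± 0.49 (SE), and the transferrin receptor Tfrc rose by 1.00 ± 0.26. Control mouse 4 had Slc46a1 at 4.13, among the heme mice, so that 2 of 9 heme mice lay under all controls, and with the smooth muscle covariate the Slc46a1 difference was -1.80. The ferritin heavy chain Fth1 (-0.01 ± 0.05) and the iron exporter Slc40a1 (-0.01 ± 0.09) were not called. Xenobiotic metabolism genes were split, 4 up and 7 down of 19 (camera, adjusted p = 0.398, and 0.0225 with the smooth muscle covariate), with the sulfotransferases Sult1c2 (-1.73 ± 0.17) and Sult1a1 (-1.66 ± 0.13) below all controls in all 9 heme mice.

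Heat shock and unfolded protein genes counted 7 up and 1 down of 16 (camera, adjusted p = 0.136), and the list was called with the replicate block (0.0301) and with the smooth muscle covariate (0.0155). Asparagine synthetase (Asns) rose by 0.82 ± 0.09 (SE) and Sdf2l1, of the endoplasmic reticulum, by 0.81 ± 0.16, while Xbp1 fell by 0.30 ± 0.07. Of 12 p53 targets 2 rose and 5 fell (camera, adjusted p = 0.297). The death receptor Fas fell by 1.12 ± 0.17 and the pro-apoptotic Pmaip1 by 0.77 ± 0.16, a call lost with the smooth muscle covariate (-0.58, adjusted p = 0.0708). The other falls were Bbc3 (-0.52 ± 0.12), Plk2 (-0.45 ± 0.12) and Ei24 (-0.13 ± 0.05), and the rises were Cdkn1a (0.42 ± 0.08) and Perp (0.22 ± 0.05). Apoptosis genes numbered 6 up and 8 down of 19 (camera, adjusted p = 0.664), with Birc5 and the pro-apoptotic Bak1 (1.85 ± 0.36) the largest of those that rose.

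Of 8 inflammation and defence genes over the floor, Slpi rose, while Saa3, Saa2 (-1.07 ± 0.15, SE), Saa1 (-1.02 ± 0.15) and the immunoglobulin receptor Pigr (-0.37 ± 0.05) fell (camera, adjusted p = 0.297). The mean of the list was 0.29 and its median -0.23, since Slpi alone outweighed the falls in the mean. Of 14 interferon response genes 5 fell and none rose, Ifit1 by 2.57 ± 0.49, the immunoproteasome subunit Psmb8 by 1.91 ± 0.49, Irf7 by 1.20 ± 0.19, Irf1 by 0.71 ± 0.16 and Ifih1 by 0.54 ± 0.09. Ifit1 and Psmb8 were under all controls in 8 of 9 heme mice. Psmb8 was at -1.13 with probe sets averaged, where only 1 of its 2 probe sets lay over the floor on enough arrays. It was at -1.60 and no longer called with the smooth muscle covariate (adjusted p = 0.110). The list was lower than other genes (camera, adjusted p = 0.0319), with adjusted p = 0.582 with an estimated correlation. Heme mouse 6 had a mean of 8.31 over the list, against 5.84 to 6.44 in the other heme mice and 7.22 ± 0.13 (SD) in controls, and without it and control mouse 2 the adjusted p was 4.61e-04. Without control mouse 2 alone it was 0.0573, and with the smooth muscle score as a covariate 0.0512, in a range of 1.76e-04 to 0.582 over all camera alternatives. Without heme mouse 6 the adjusted p was 1.76e-04 and 12 interferon response genes were lower. None of 4 MHC class II genes was called, and their median was -0.26. Of 12 circadian clock genes 7 fell and 1 rose (camera, adjusted p = 0.134, and 0.0301 with the replicate block), the output factor Dbp by 2.86 ± 0.79 and the period gene Per3 by 2.18 ± 0.44, while the repressor Cry1 rose by 1.06 ± 0.25.

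Among the cells of the epithelium, endocrine and tuft cell markers fell. Of 9 enteroendocrine markers 6 fell and none rose, with a median of -0.98, Chga most and Tph1, the serotonin synthesis enzyme of enterochromaffin cells, by 2.37 ± 0.20 (SE). The hormone genes Pyy (-0.19 ± 0.12), Gcg (-0.11 ± 0.12) and Insl5 (0.69 ± 0.75) were not called, and Insl5 was at 4.16 in control mouse 4 against 7.90 to 10.78 in the other controls. All 3 tuft cell markers over the floor fell, Dclk1 by 1.40 ± 0.17, Avil by 0.79 ± 0.11 and Trpm5, which lay under the floor in all heme mice, at least 1.42-fold. Their median was -1.21, or -0.79 with Trpm5 at its bound. Trpm5 passed the signal filter only through the controls, so its fall is not independent support for the list. Both lists were lower than other genes (camera, adjusted p = 0.0017 and 0.00546). With an estimated correlation they gave adjusted p = 0.205 and adjusted p = 0.185, and without control mouse 4 the tuft cell list gave adjusted p = 0.0532, in a range of 8.49e-04 to 0.185 over its camera alternatives. Of 15 goblet cell markers 9 fell and 1 rose, with a median of -0.19 (camera, adjusted p = 0.0681). The goblet cell list was called without a signal filter (0.013) and with the replicate block (0.047). The antimicrobial Ang4 fell by 2.29 ± 0.50, and the mucin Muc2 by 0.19 ± 0.04, but with the smooth muscle covariate Ang4 was no longer called (-0.73, adjusted p = 0.327). The resistin-like Retnlb rose by 0.89 ± 0.34 (adjusted p = 0.0381, limma), with no heme mouse above all controls. That call was lost without control mouse 1, 3, 4 or 7 or heme mouse 2, 4, 7, 8 or 9, each left out singly, where the difference was between 0.69 and 0.88. It was also lost with the replicate number as a block (adjusted p = 0.110), without a signal filter (0.0548), with trend and robust variance (0.0537) and with the distal Hox covariate (0.0779), and with the smooth muscle covariate Retnlb was at 1.86. Surface colonocyte markers were split, 8 up and 6 down of 23 (camera, adjusted p = 0.538), with the chloride channel regulator Clca4a (1.42 ± 0.16) and the water channel Aqp8 (1.30 ± 0.14) the largest rises. Clca4a has close relatives that its probe set can bind.

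Markers of other cell types that a scraping can hold moved unevenly. The 3 tested T cell and intraepithelial lymphocyte markers fell, with Gzma joined by the chemokine Ccl5, at least 3.27-fold lower, and the receptor Klrd1, at least 1.69-fold lower, both under the floor in all heme mice. Of 12 annotated markers only these 3 were tested. Ccl5 and Klrd1 passed the signal filter only through the 6 controls, so they could only fall. The test of the list is therefore not independent support. Leaving out any 1 control mouse left 1 of the 3 over the floor on enough arrays. Their median was -2.85, or -1.71 with members under the floor at their bound (camera, adjusted p = 0.00127, and adjusted p = 0.185 with an estimated correlation). All 5 smooth muscle markers fell, Myh11 by 2.45 ± 0.39, with a median of -2.00 (camera, adjusted p = 0.0198, and adjusted p = 0.459 with an estimated correlation). The smooth muscle list gave adjusted p = 0.0559 when probe sets of a gene were averaged, in a range of 3.95e-04 to 0.618 over its camera alternatives. Control mouse 2 had a smooth muscle mean of 9.45, against 7.30 ± 1.17 (SD) in all controls and 5.37 ± 0.62 in heme mice. Kit, which mast cells and other intestinal cells express, fell by 1.28 ± 0.18. The mast cell proteases Mcpt1 (mean 2.96 in control, 4.62 in heme mice) and Mcpt2 (2.87 and 4.37) were over the floor on too few arrays to be tested. None of 7 fibroblast markers was called (median 0.07), nor of 5 macrophage markers (0.22) or 2 B and plasma cell markers (0.45). With the smooth muscle covariate these 3 lists were called higher (adjusted p = 0.0042, 0.0201 and 0.046). The smooth muscle score itself differs between the groups. Control mouse 2 was high in it and in the fibroblast (9.58), macrophage (8.12) and B and plasma cell (9.80) means. These calls can therefore not be read as a response to heme. Of 3 adipocyte markers Cidec, a lipid droplet protein, rose by 2.86 ± 0.28, while Adipoq (-0.36 ± 0.85) and Fabp4 (-0.17 ± 0.52) were not called. Of 2 squamous markers Sprr1a rose and Krt10 was not called (0.01 ± 0.09). No endothelial, nerve or erythrocyte marker was over the floor on enough arrays. As a sign of RNA integrity, the 3-prime minus 5-prime log2 difference of the Gapdh control probe sets was compared, with a value of -0.05, heme minus control (exact two-sided permutation p = 0.0645, n = 6 and 9), and that of beta-actin -0.06 (exact p = 0.175). Adjusted for both tests these were 0.129 and 0.175.

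**Figure D3:**
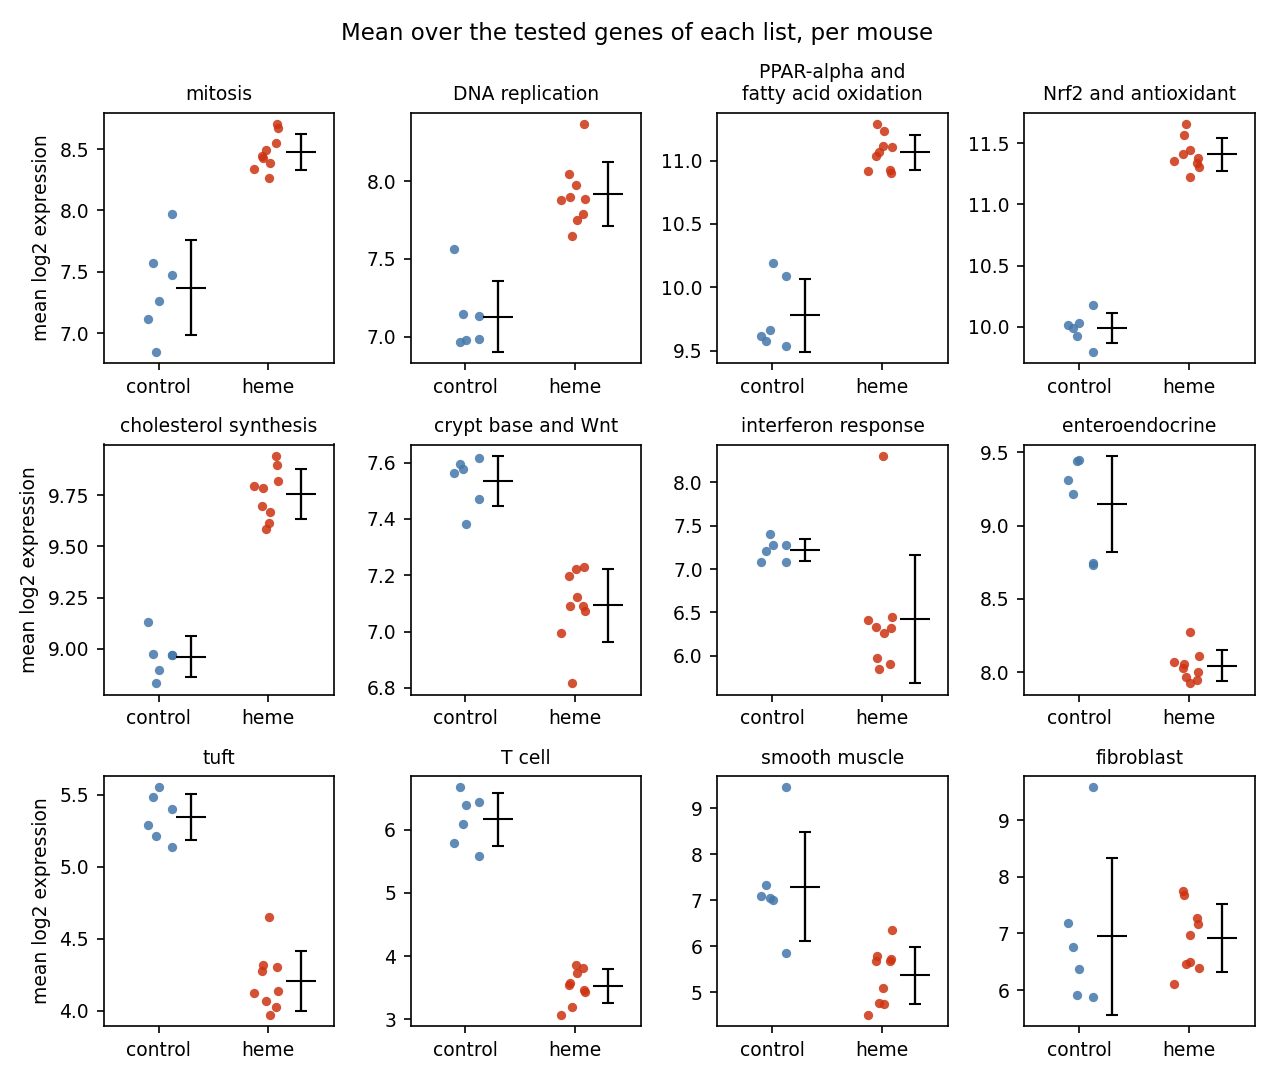
Each panel plots the mean log2 expression over the tested genes of 1 list, with a point per mouse and a line at the group mean with its SD (6 control, 9 heme mice); each panel has its own vertical scale. Mitosis, DNA replication, PPAR-alpha, Nrf2 and cholesterol lists are higher in all heme mice than in all controls, heme mouse 6 stands at 8.31 in the interferon panel, and control mouse 2 at 9.58 in the fibroblast panel.

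**Figure D4:**
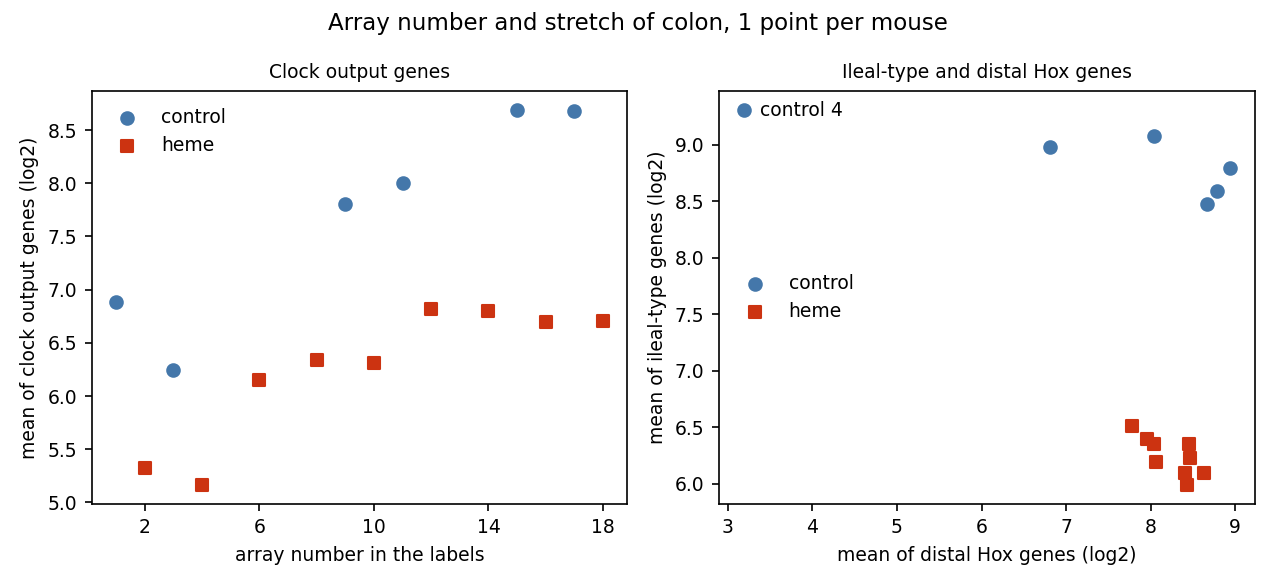
Left, the mean log2 expression of 6 clock output genes against array number; right, the mean of 12 ileal-type genes against the mean of 3 distal Hox genes, with a point per mouse (6 control, 9 heme). Clock output rises with array number in both groups and is lower with heme, and control mouse 4 stands apart on the right at a distal Hox mean of 3.19.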

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

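The tests with a distal Hox or small intestine covariate, and of the clock and the smooth muscle markers, and the alternatives that leave out mice together or use a smooth muscle or distal Hox covariate, were chosen after the results were seen. Among 100 splits of the 15 mice into 6 and 9, only the real split (1 of 100) gave as many genes higher (2516 against a highest other of 0), lower (2445 against 0) or changed at least 2-fold (506 against 0). With 100 splits drawn, 1 in 100 is the least that this can show. Splits that mix the groups also carry the difference between them as spread, which lowers their calls. For the number of gene lists called chance cannot be excluded, since 10 of the 100 splits, the real one included, gave 12 or more and the highest other gave 16. That split kept 4 of the 6 controls together, so it still carries part of the real contrast.

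A mouse far from the rest of its group was found in 18 of 186 sets of values, 8 in the heme group and 10 in the control group, where chance gives about 1 in 20. Control mouse 2 was high for fibroblast markers (9.58, others 5.87 to 7.18), B and plasma cell markers (9.80, others 6.44 to 7.66), MHC class II presentation (10.64, others 8.36 to 8.99) and the BMP pathway (8.58, others 8.02 to 8.19). It was low for Il15 (7.95, others 8.42 to 8.64), Sult1c2 (9.28, others 9.87 to 10.01) and Kit (9.10, others up to 10.35). Control mouse 4 was low for Slc46a1 (4.13, others 6.90 to 8.56) and Ptch1 (9.04, others 9.37 to 9.48), and control mouse 3 was high for DNA replication (7.56, others 6.97 to 7.15). Heme mouse 6 was high for the interferon response (8.31, others 5.84 to 6.44), Psmb8 (9.59, others 5.33 to 7.03), Sult1a1 (12.01, others 10.86 to 11.43) and Slc46a1 (5.21, others 3.96 to 4.37), and low for Ereg (4.63, others 6.23 to 7.39). Heme mouse 5 was low for Il15 (4.36, others 5.96 to 7.24) and Cidec (7.52, others 8.01 to 8.34), and heme mouse 1 was high for Fabp6 (8.35, others 7.03 to 7.49). Among 1672 tested probe sets with no listed gene, 191 were higher with heme and 710 lower.

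Of 12 genes of bile acid handling, nutrient transport and other functions, here called ileal-type, 11 were lower with heme, with a median log2 fold change of -2.70. They were put together after their values were seen, so that their count is no test of enrichment. The 12 did not move as 1 set in control mouse 4. It was the highest control for Fabp6 (12.14) and Cubn (9.94) but the lowest for Slc46a1 (4.13, other controls 6.90 to 8.56). Small intestinal tissue in the control scrapings as the whole cause was checked with 8 tested small intestine genes, of which 4 fell and 1 rose. Their median was -0.34 ± 0.38 (SE over genes, not over mice), and a high level of these in colon could hide a small share. With the mean of the 10 under the signal filter as a covariate the ileal-type difference was -2.59 ± 0.15, so their level does not account for it. Most of the 10 lie near background, so this covariate is a weak guide and small intestinal tissue stays open. More proximal colon in the control scrapings stays open, since 3 distal Hox genes had a median of 0.92 with a standard error across mice of 0.73, a form of error chosen after the value was seen, and without control mouse 4 the Hox difference was -0.003 ± 0.31. With the mean of these 3 distal Hox genes as a covariate the ileal-type mean still differed by -2.52 ± 0.09, so their level does not account for the difference. Since their own group difference rests on control mouse 4, this covariate cannot decide whether a more proximal stretch was the whole cause. More anterior Hox genes were not part of it. The more anterior genes Hoxb5 (-1.68 ± 0.19) and Hoxb6 (-0.90 ± 0.22) were lower with heme, and control mouse 4 was high for the small intestinal Apoa1 (9.94, other controls 2.38 to 7.27, heme mice at most 3.10) and Anpep (8.69, others 3.15 to 7.64, heme mice at most 3.63) but not Apoa4 (3.32, others 2.39 to 4.88), so a part played by region, or a response to heme in these genes, may both be at work.

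Clock output genes were lower with heme (-1.46 ± 0.41, SE, in their mean) and rose with array number within both groups. Pearson's r was 0.946 in control mice (exact permutation p = 0.0139, Spearman's rho 0.886, exact p = 0.0333) and 0.872 in heme mice (permutation p = 0.00144, rho 0.817, permutation p = 0.0102), and 0.971 and 0.853 without the 2 farthest mice. Opposite-phase genes gave r of -0.933 and -0.908 (exact or permutation p = 0.0125 and 0.00109, rho -0.943 and -0.85, p = 0.0167 and 0.0062, r -0.919 and -0.843 without the 2 farthest), and over the 4 relations the adjusted p of r was 0.0139 in control and 0.00288 in heme mice. With array number as a covariate the output difference was -1.54 ± 0.19, which argues against drift with array number as the whole cause. With the opposite-phase mean as a covariate it was -1.10 ± 0.19. That mean covers 2 genes, Arntl and Npas2, neither of them called (limma, adjusted p = 0.199 and 0.779). The opposite-phase mean differed by 0.31 ± 0.33, heme minus control. At a given array number it was higher with heme by 0.37 ± 0.15, as a shift of phase would also give. The same clock sampled at another time therefore stays open, as may an effect of heme on the clock.

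Smooth muscle markers were lower with heme (-1.92 ± 0.46, SE, in their mean) while fibroblast markers were not called (-0.03 ± 0.52). With the fibroblast mean as a covariate the smooth muscle difference was -1.90 ± 0.29, which argues against less muscle and stroma together as the whole cause. Without control mouse 2 it was -1.49 ± 0.34, so this mouse is not the whole cause. A difference in how deep the scrapings reached that brings muscle without fibroblasts may still play a part, and a response of the tissue to heme stays open.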

How the results depend on the processing

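The alternatives that leave out mice together, and the smooth muscle and distal Hox covariates, were chosen after the data were seen. Of 1702 comparisons of a named gene under an alternative, 1678 kept direction and side of the threshold. Under the alternatives fixed beforehand that keep all mice, 61 of the 63 named genes did so wherever they were tested, and likewise 61 when any 1 mouse was left out, Retnlb and Ppara being the others. Only 44 were tested at a floor of 100, 56 with averaged probe sets and 59 to 63 without 1 mouse. With the smooth muscle covariate Bmp2 (-0.51, adjusted p = 0.0527), Pmaip1 (-0.58, 0.0708), Psmb8 (-1.60, 0.110) and Ang4 (-0.73, 0.327) were no longer called. Most named genes were chosen for large called changes, so their stability does not stand for that of all called genes. Of the 4961 genes called, 62.8% kept call and direction with the smooth muscle covariate and 77.0% with the replicate block. With averaged probe sets 78.2% did so and at a floor of 100 78.6%, both with fewer genes tested. The counts of genes higher and lower stayed within 1.5 times of 2516 and 2445. Leaving out 1 mouse gave 2332 to 2557 higher and 2152 to 2517 lower.

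At a floor of 100, 331 genes changed at least 2-fold and 3 lists were lower, with fewer genes tested. The crypt base and Wnt target list then had adjusted p = 0.258, and EGF receptor ligand and receptor (0.489) and apoptosis (0.742) reversed, neither called. With the smooth muscle covariate 9 lists were higher, the crypt base and Wnt target list had 0.0535 and interferon response 0.0512, and EGF receptor ligand and receptor (0.733), MHC class II presentation (0.120) and smooth muscle (0.618) reversed, the last because its own mean was the covariate. Lists that gained a call with this covariate were fibroblast (0.0042), macrophage (0.0201), B and plasma cell (0.046), xenobiotic metabolism (0.0225) and heat shock and unfolded protein response (0.0155). The smooth muscle score itself differs between the groups, so calls gained with it can not be read as a response to heme. With an estimated correlation 0 lists were higher and 0 lower, with 0.14 for study-named inhibitors of proliferation and Nrf2 target and antioxidant, 0.224 for mitosis and cell division, 0.234 for DNA replication, 0.219 for crypt base and Wnt target and PPAR-alpha target and fatty acid oxidation, 0.185 for cholesterol synthesis, tuft cell, T cell and intraepithelial lymphocyte, 0.582 for interferon response, 0.205 for enteroendocrine cell and 0.459 for smooth muscle. With the replicate block Hedgehog pathway (0.0496), heat shock and unfolded protein response (0.0301), circadian clock (0.0301) and goblet cell (0.047) were called, and without a filter Hedgehog pathway (0.0396) and goblet cell (0.013). With fry, which tests against no change, 10 lists were higher and 12 lower. With the mean of probe sets smooth muscle had 0.0559. Fibroblast markers, not called, reversed with the mean of probe sets (0.943), no filter (0.623), the replicate block (0.715) and the distal Hox covariate (0.771). Without 1 mouse the adjusted p ran from 1.76e-04 to 0.0573 for interferon response (highest without control mouse 2) and from 0.00296 to 0.0532 for tuft cell (highest without control mouse 4). Over the same settings EGF receptor ligand and receptor ran from 0.676 to 0.979, MHC class II presentation from 0.500 to 0.950 and fibroblast from 0.255 to 0.991. EGF reversed without control mouse 2 or 6, MHC class II without control mouse 2, and fibroblast without control mouse 1, 4, 6 or 7 or heme mouse 3, 5, 7, 8 or 9. The cause was not tested except where stated. Some lists had under 2 tested members, and so no value, at a floor of 100, with averaged probe sets, without several mice or, for the T cell list, without any 1 control mouse. The replicate numbers do not pair the mice (r -0.195 to 0.196 over 6 shared numbers), and with them as a block 3964 genes were called, 3821 of them shared. Heme mice 5, 8 and 9 have no control of the same number, so results with the block rest on the other mice. Genes near the signal floor limit what could be tested.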

Other observations

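The gene groups here were put together after their values were seen, so their counts are not a test. Genes of serine and amino acid synthesis and uptake were higher with heme in 8 of 10 tested, with Psat1, an enzyme of serine synthesis, at a log2 fold change of 2.05 ± 0.17 (SE) and the transporter Slc1a4 at 1.89 ± 0.19. Genes known from stratified or injured epithelium were higher in 11 of 12 tested, among them the urokinase receptor Plaur (2.64 ± 0.17), and, under the floor in all controls, the water and glycerol channel Aqp3 (at least 5.39-fold higher) and Trim29 (at least 2.90-fold higher), and Krt7 was lower (-0.41). Of 12 metal transport and metallothionein genes 4 rose and 5 fell, with Mt4 (at least 2.20-fold, under the floor in all controls), Mt2 (1.20 ± 0.28) and Mt1 (0.93 ± 0.19) higher and Slc30a10 and Slc39a14 (-0.83) lower.

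The spread between mice was larger in the control group in 61.1% of tested genes, and in 52.2% without control mouse 2. Control mouse 4 had the distal colon transcripts Hoxd13 at 1.74 against 7.57 ± 1.15 (SD, n = 5) in the other controls and Atp12a at 5.02 against 12.21 ± 0.83. Heme mouse 6 had Cxcl9 at 5.49 against 2.51 ± 0.24 in the other 8 heme mice and Tap1 at 7.51 against 4.43 ± 0.24.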
